A study of Homo sapiens with 16 samples.

How the data were processed

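Total RNA of MCF-7 cells was labelled with biotin and hybridised to Affymetrix oligonucleotide arrays, 16 in all, with 4 for each of 4 groups. Per the labels' protocols the medium held 0.5% charcoal-treated serum from the day before treatment, cycloheximide (10 µg/ml) or its solvent was added 1 h before E2 (25 nM) or ethanol, and cells were collected after 24 h. Groups and replicate numbers were taken from the sample titles.

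The deposited values are log2 expression levels per probe set made by the authors with RMA, as named in the labels, which corrects background, normalises between arrays and summarises the probes of a set. The labels do not give the version of RMA or its settings. The log base is not stated in the labels and was read from the values: they run from 2.21 to 14.1, and a natural log of 14.1 would lie above the ceiling of a 16-bit scanner (65536). No value was missing and no arrays held identical values. RMA makes the distributions of all arrays nearly the same, so a change common to most transcripts cannot be seen in these values. The number of arrays limits the precision that can be stated for them, and so do the scaling of the arrays and the choice of probe set. No scan dates or batches were in the files used here, and no batch could be tested.

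Of 54675 probe sets 62 were array controls. The platform annotation gave 1 gene symbol for 41091 probe sets, several for 1801 and none for 11721. Current symbols were looked up by Entrez identifier for 41037 of these probe sets and none needed a change. Each of 19775 genes was represented by its probe set with the highest mean over the 16 arrays, with no filter on dim genes. Where other probe sets of a named gene passed in the opposite direction this was counted: 0 of 103 genes for E2 without cycloheximide, 1 of 96 for E2 with cycloheximide (BCL2), 0 of 94 for the interaction, 6 of 120 for cycloheximide without E2 (RPS29, YARS1, SEC61B, BAD, BCL2 and FOXA1) and 2 of 114 for cycloheximide with E2 (RRP12 and YARS1).

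One linear model with a mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 12 residual degrees of freedom. The contrasts were E2 minus vehicle, the same with cycloheximide, their difference (the interaction), and cycloheximide minus vehicle without and with E2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Calls shared by the E2 contrasts were compared with the overlap of independent lists, the product of their sizes over the number of genes, per direction. These contrasts have no array in common.

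Gene lists (24) were written from general knowledge before the data were examined, as were the contrasts, the rule for named genes and all alternatives except array weights. Several lists share members. Lists were tested per contrast with camera at a preset inter-gene correlation of 0.01 and adjusted over the 24 lists, with the correlation estimated from the data as a second value. With the preset value 16, 10, 17, 12 and 12 lists passed in the 5 contrasts in the order above, and 8, 2, 9, 3 and 7 with the estimated one. The median, the mean and the camera direction of a list differed in sign for 1, 5, 3, 4 and 3 lists: luminal identity for E2 without cycloheximide; proliferation inhibitors, ribosomal proteins, BCL2 family, luminal identity and proteasome for E2 with it; ribosome biogenesis, NF-kB targets and basal markers for the interaction. For cycloheximide without E2 these were proliferation inhibitors, BCL2 family, luminal identity and hypoxia, and with E2 ATF4 targets, basal markers and fibroblast and immune markers.

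Named genes were, for both E2 effects and the cycloheximide effect without E2, the 10 with the largest increase and the 10 with the largest decrease among genes with an adjusted p under 0.05, a mean above the median gene level (5.77) and no overlap between the arrays of both groups. For the interaction and for cycloheximide with E2 the 5 largest in each direction were taken. For the interaction, no overlap was required in at least 1 of both E2 contrasts. Always reported were TFF1, PGR, GREB1, PDZK1, CXCL12, MYB, MYC, CCND1, ESR1, IGFBP4, XBP1, CA12, NRIP1, E2F1, CCNE2, CDC6, CCNB1, ERBB2, CCNG2 and BMF. For each list and contrast up to 2 members with the largest called increase and up to 2 with the largest called decrease were added, or, where none passed, the 2 brightest.

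The alternatives were the replicate number as a block, a fit of only the groups of the contrast, a trended and robust variance prior, the mean of all probe sets of a gene, leaving out probe sets with an _x_at or _s_at suffix, testing every probe set, leaving out genes at or below the median level, centring each array on its median, centring it on the mean of 18 hybridisation control probe sets (bioB, bioC, bioD and cre), a 2-fold minimum, leaving out each array in turn, and array weights. The hybridisation controls are RNAs added before hybridisation, and centring on them can carry their own noise into every gene. The 3' minus 5' gaps of the GAPDH and ACTB controls served as measures of RNA quality.

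The pipeline was tested on simulated normal data with the vehicle means and residual spreads of the real genes and 200 changed genes among 19775. Of changes of 0.5 on the log2 scale it recovered 85.1% for E2 without cycloheximide, 83.6% for E2 with cycloheximide, 58.2% for the interaction, and 88.1% for cycloheximide without and with E2. Of changes of 1 it recovered 100%, 98.5%, 95.5%, 100% and 100%. The share of calls that were false was 2.06%, 5.53%, 5.59%, 6.34% and 9.0%. Figures were drawn with matplotlib 3.10.9.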

Results

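The data were transcript levels of MCF-7 cells, an established line of luminal breast carcinoma that grows in response to estrogen through the estrogen receptor alpha (ESR1). Cells kept in steroid-depleted medium received vehicle or estradiol (E2, 25 nM) for 24 h. Cycloheximide, an inhibitor of translation elongation, was given at 10 µg/ml 1 h before the hormone to some of the groups, so that the 4 groups formed a factorial design with 4 arrays each: vehicle, E2, cycloheximide, and cycloheximide with E2. The question put by this design was which transcripts change with E2 when new protein synthesis is inhibited. Levels are log2 values with the SD over 4 arrays, changes are log2 differences with their SE from limma, and rose and fell are used of genes with an adjusted p under 0.05.

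The 16 arrays held 54675 probe sets, from which 19775 genes were taken. Array medians lay between 4.72 and 4.79. The mean levels of TMPRSS3, PDZK1, IL1R1, EGR3, CCN2, LINC01588, VXN, CDH26, BLNK, RGCC, LAMB1, COXFA4L3, H2BC4 and SKP2 lay below those of their arrays in at least 1 group, where signal above background is not shown, so their folds and ranks rest on an uncertain low level. The first principal component carried 69.9% of the variance and parted the arrays by cycloheximide. The second, with 12.8%, parted them by E2. Vehicle replicate 1 stood farthest from its group, with a mean correlation of 0.9935 to the other vehicle arrays against 0.996 to 0.9977 for the remaining 15 arrays and a median absolute deviation of 0.131 against 0.0752 to 0.0927. The labels name replicates without saying that they were separate cultures, so p-values measure the spread between these samples, which may be technical.

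E2 alone raised transcripts of DNA replication, mitosis and hormone response and lowered a set of genes active in the hormone-deprived cells. Among genes above the median level, MYBL1, a transcription factor of the MYB family, rose most, from 5.53 ± 0.68 to 9.32 ± 0.12 (log2 change 3.79, SE 0.22). The kinase inhibitor gene PKIB rose 7.09-fold, from 7.57 ± 0.18 to 10.40 ± 0.15. The progesterone receptor gene PGR rose 5.19-fold, from 5.99 ± 0.44 to 8.36 ± 0.13. The replication initiation factor MCM10 rose 4.96-fold, and EXO1, an exonuclease of DNA repair, rose 4.54-fold. The GABA receptor subunit gene GABBR2 fell 5.42-fold, from 8.65 ± 0.17 to 6.21 ± 0.21.

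Under the same limit on level and with no overlap between groups, the other genes with the largest increases were UGT2B15, SYTL4, TMPRSS3, PCP4 and DSCC1, with log2 changes between 2.26 and 2.63. Probe sets with an _x_at or _s_at suffix can share sequence with other transcripts. With such probe sets left out the changes were -0.090 for UGT2B15, 0.073 for TMPRSS3 and 0.24 for DSCC1, with adjusted p = 0.577, 0.694 and 0.0557. Here and below, a probe set that replaces one with such a suffix is dimmer, since the brightest was taken first. Its level was not compared with background, so a change missing there does not by itself show that the first reading was false. SYTL4 was lowest on vehicle replicate 1, at 4.56 against a mean of 5.47 on the other vehicle arrays. Under the same limits on level and overlap, the largest decreases after GABBR2 were those of AHRR (-1.99), a repressor of the aryl hydrocarbon receptor, UPK1A (-1.93) and GRHL3 (-1.91). Then came STON1 (-1.77), TNS3 (-1.70), PSCA (-1.66), SALL4 (-1.60), CYP1A1 (-1.53) and SNAI2 (-1.48).

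Among the genes reported whatever their values, the trefoil factor TFF1 was already at 12.70 ± 0.06 with vehicle and rose to 13.27 ± 0.02. GREB1 rose from 8.46 ± 0.19 to 10.11 ± 0.06 (log2 change 1.65, SE 0.078), the chemokine CXCL12 2.44-fold, XBP1 2.24-fold, MYB 2.01-fold and NRIP1 1.49-fold, and PDZK1 from 4.12 ± 0.36 to 4.94 ± 0.031. CA12 rose from 9.15 ± 0.092 to 10.15 ± 0.036. Of the cell cycle genes, CCNE2 rose 3.69-fold, CDC6 3.49-fold, CCNB1 1.62-fold and E2F1 1.46-fold. BMF, CCNG2 and ERBB2 fell, with log2 changes of -1.02, -0.93 and -0.86. ESR1 itself was lower by -0.22 (SE 0.05, adjusted p = 0.00291), a call that ended with the mean of its probe sets (-0.052, adjusted p = 0.619) and with centring on the hybridisation controls (-0.099, adjusted p = 0.524). MYC was higher by 0.17 (SE 0.05, adjusted p = 0.0204), which did not pass without E2 replicate 1 (0.15, adjusted p = 0.0718), without vehicle replicate 3 (0.14, adjusted p = 0.0709), with only the 2 groups in the fit (adjusted p = 0.0566) or with control centring (0.29, adjusted p = 0.057). CCND1 (0.12, adjusted p = 0.2) and IGFBP4 (0.13, adjusted p = 0.173) did not pass, whereas the mean of the CCND1 probe sets did (0.24, adjusted p = 0.0041).

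Of 45 measured DNA replication genes 44 rose with E2 and none fell, with a median log2 change of 1.30 (44 adjusted over the list alone). Of 39 mitosis genes 38 rose (39 adjusted over the list alone), with a median of 1.24, and NUF2, a kinetochore component, and ANLN, a scaffold of cytokinesis, rose most, by 1.81 and 1.74. Of 19 G1/S regulators 17 rose and CDK6 fell by 0.94 (the same counts adjusted over the list alone). Camera adjusted p-values of these 3 lists were 2.75e-54, 7.61e-40 and 4.35e-18, and 0.0042, 0.0174 and 0.00128 with an estimated correlation. Of 38 E2-induced genes known from earlier work 30 rose and 3 fell (31 and 3 adjusted over the list alone), with an adjusted p = 0.00128 with an estimated correlation. HSPB8 and FHL2, which fell by 0.28 and 0.25, went against the name of their list and did not pass with control centring (adjusted p = 0.274 and 0.37). Of 20 E2-repressed genes 19 fell, with the interleukin receptor gene IL1R1 lowest at -2.75 (19 adjusted over the list alone; adjusted p = 9.1e-05 with an estimated correlation). These 2 lists came from knowledge of this and similar cell lines, so their direction was not independent evidence.

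Cholesterol synthesis genes rose in 11 of 19 cases and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.0227 with an estimated correlation), with ACAT2 and EBP higher by 1.07 and 0.89. Of 24 p53 targets 11 fell and 3 rose (12 and 3 adjusted over the list alone; adjusted p = 0.0123 with an estimated correlation), TP53INP1 most, by -1.45. Of 18 proliferation inhibitors 10 fell and 3 rose (12 and 3 adjusted over the list alone; adjusted p = 0.0472 with an estimated correlation), among them the CDK inhibitor genes CDKN2B, which fell by 1.17, and CDKN1B, which rose by 0.27. Interferon response genes fell in 19 of 26 cases (23 adjusted over the list alone) with a median of -0.39, OAS2 and MX1 most (-0.92 and -0.87). Camera gave an adjusted p = 3.79e-10 with the preset correlation and an adjusted p = 0.206 with an estimated correlation.

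The call of 7 further lists was likewise lost with an estimated correlation. Ribosome biogenesis genes rose in 17 of 36 cases and fell in 1 (21 and 1 adjusted over the list alone; adjusted p = 0.155 with an estimated correlation), FBL most, by 0.35. Proteasome subunits rose in 12 of 27 cases (13 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation). Hypoxia and glycolysis genes rose in 13 and fell in 6 of 23 cases (the same adjusted over the list alone; adjusted p = 0.195 with an estimated correlation). Immediate early genes fell in 15 and rose in 7 of 33 cases (15 and 8 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), with EGR3 and FOS higher by 1.98 and 1.18 and EGR1 and CCN2 lower by -0.93 and -1.28. ATF4 targets fell in 9 and rose in 4 of 22 cases (9 and 5 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), and their median of -0.10 became 0.0155 with control centring. Histone genes fell in 9 and rose in 5 of 21 cases (9 and 6 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation). Their median of -0.007 became 0.11 with control centring and was above 0 without E2 replicates 2 (0.031) or 3 (0.004) or vehicle replicates 1 (0.053) or 4 (0.019). Basal and myoepithelial markers fell in 4 and rose in 1 of 10 cases (5 and 1 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation).

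No call was made for 8 lists with E2 alone. With limma 0 of 53 ribosomal protein genes passed (0 adjusted over the list alone, 2 at an unadjusted p under 0.05). RPL41, the brightest, differed by less than its SE. It lay next to the highest value of 14.1 (14.06 with vehicle, 14.05 with E2), where distributions made alike by RMA leave little room for a change. Genes higher and lower with E2 numbered 2 and 3 of 15 tRNA synthetases, 7 and 4 of 19 ER chaperones, 0 and 8 of 23 NF-kB targets, 3 and 7 of 19 nonsense-mediated decay targets, 3 and 5 of 16 BCL2 family genes, 3 and 5 of 17 luminal identity genes, and 1 and 1 of 15 fibroblast and immune markers. Adjusted over the list alone these counts were 2 and 3, 8 and 4, 0 and 8, 3 and 7, 4 and 6, 4 and 7, and 0 and 1. Within the BCL2 family BCL2 and BNIP3 rose by 0.90 and 0.78, and BMF and BIK fell by 1.02 and 1.01.

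In all, 4936 of 19775 genes passed with E2 alone, 2343 higher and 2593 lower, of which 273 were at least 2-fold higher and 88 at least 2-fold lower. Centring the arrays on their hybridisation controls shifted the median of all genes from 0.012 to 0.13 and the share of calls that were higher from 47.5% to 75.2%; array median centring gave 45.5%.

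**Figure D1:**
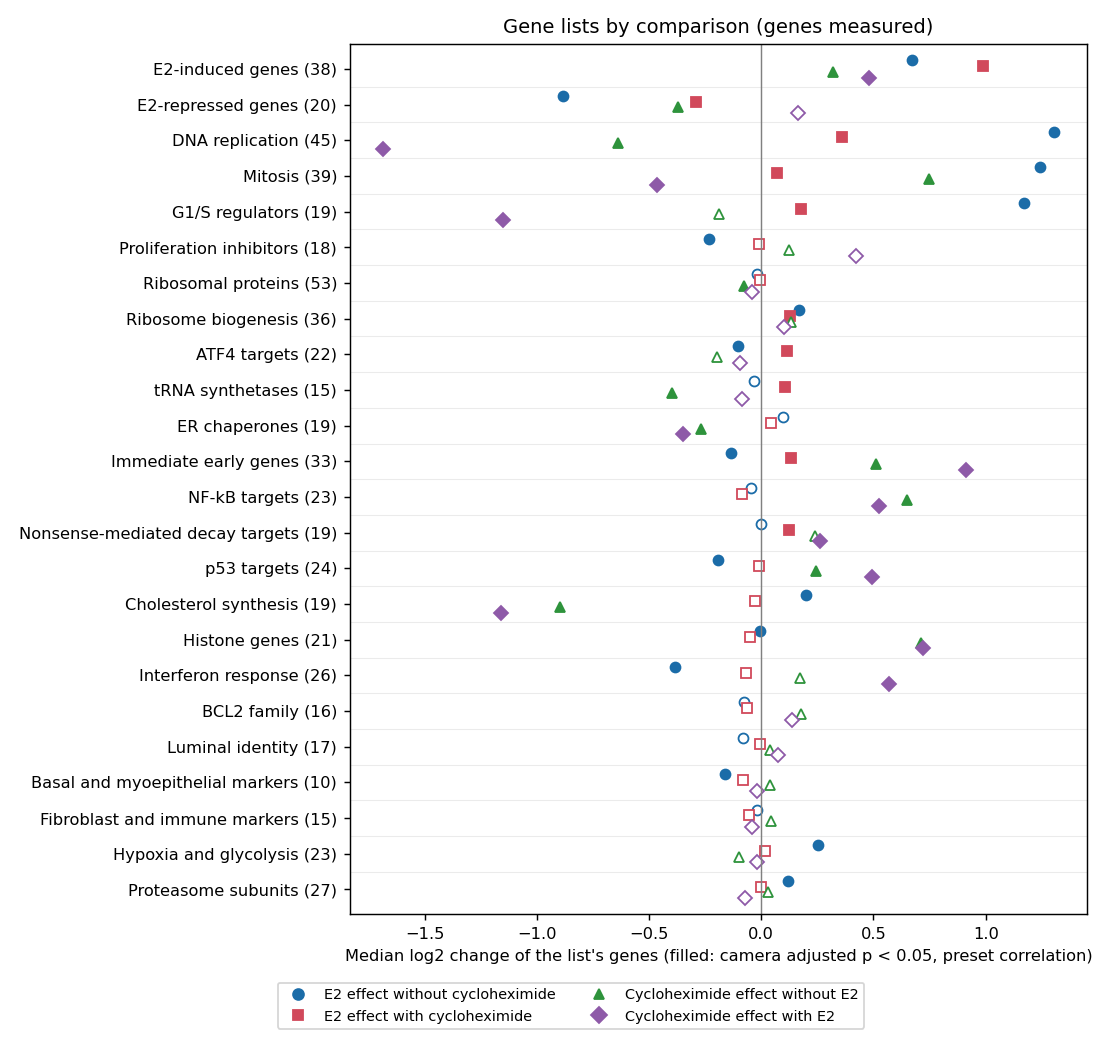
Median log2 change (x axis) of the genes of 24 lists (y axis, with the number measured) in the E2 effect without and with cycloheximide and the cycloheximide effect without and with E2; filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation. The mitosis list lies at 1.24 for E2 alone, 0.070 for E2 with cycloheximide, 0.75 for cycloheximide alone and -0.46 for cycloheximide in E2-treated cells.

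In cells given cycloheximide first, E2 raised 34 of 38 genes of the E2-induced list. Keratin 13 (KRT13) rose 15.9-fold, from 5.12 ± 0.32 to 9.11 ± 0.040 (log2 change 3.99, SE 0.12), and the noncoding RNA LINC01588 rose from 4.80 ± 0.16 to 8.71 ± 0.16. The retinoic acid hydroxylase gene CYP26B1 rose 7.46-fold and MYBL1 5.27-fold. PGR rose 5.17-fold, from 6.52 ± 0.25 to 8.90 ± 0.24. Among genes above the median level and with no overlap between groups, keratin 4 (KRT4) had the largest decrease, 3.91-fold, from 9.67 ± 0.08 to 7.70 ± 0.10.

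Further increases were those of LINC01016 (3.04), VXN (2.61), CDH26 (2.31), RBM24 (2.31) and SLC26A2 (2.29). Among genes above the median level the decreases after KRT4 were smaller, from -1.22 for RAB27B, through SOX2 (-1.15), LINC00052 (-1.14), PGM5 (-1.12), CAB39L (-1.10), ERP27 (-1.06) and GRB14 (-1.06), to ADAMTS19 (-1.05) and IDH1, from 9.47 ± 0.031 to 8.47 ± 0.023. Among the genes always reported, CA12 rose 3.43-fold, XBP1 3.13-fold, CXCL12 2.70-fold, MYB 2.62-fold, GREB1 2.15-fold, IGFBP4 1.97-fold, CCND1 1.55-fold, MYC 1.53-fold and CDC6 1.42-fold. PDZK1 rose from 3.85 ± 0.18 to 5.06 ± 0.097. TFF1 was higher by 0.22 (SE 0.05), with an adjusted p = 0.418 after control centring. ERBB2, CCNG2 and BMF fell, with log2 changes of -0.57, -0.52 and -0.45. NRIP1 (0.24), E2F1 (0.18), CCNE2 (0.18), CCNB1 (0.012) and ESR1 (-0.043) did not pass, with adjusted p between 0.146 and 0.939.

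The E2-induced list was called with cycloheximide too, with 34 genes higher and 1 lower (36 and 1 adjusted over the list alone), a median of 0.99 and an adjusted p = 4.08e-05 with an estimated correlation. TFF3 was the member that fell, by 0.27. The E2-repressed list had 14 lower genes and 1 higher (16 and 1 adjusted over the list alone; adjusted p = 0.0044 with an estimated correlation), with BLNK lowest at -0.94 and KRT15 higher by 1.36. Of 45 DNA replication genes 30 rose (36 adjusted over the list alone), with a median of 0.36 and an adjusted p = 0.0839 with an estimated correlation. Of 39 mitosis genes 2 rose, MAD2L1 and CDCA8 (1 adjusted over the list alone; adjusted p = 0.69 with an estimated correlation), and neither passed after control centring (adjusted p = 0.139 and 0.322). G1/S regulators rose in 5 cases and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation).

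Calls with the preset correlation alone were also made for 5 lists in the presence of cycloheximide, in each of which only some members passed. Immediate early genes rose in 15 and fell in 4 of 33 cases (16 and 4 adjusted over the list alone; adjusted p = 0.0839 with an estimated correlation), ribosome biogenesis genes rose in 13 of 36 (16 adjusted over the list alone; adjusted p = 0.0839 with an estimated correlation), and ATF4 targets rose in 8 and fell in 2 of 22 (10 and 2 adjusted over the list alone; adjusted p = 0.111 with an estimated correlation). Nonsense-mediated decay targets rose in 2 and fell in 1 of 19 cases (2 and 1 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation), and 1 of 15 tRNA synthetases rose (1 adjusted over the list alone; adjusted p = 0.429 with an estimated correlation). No call was made for the other 14 lists, among them cholesterol synthesis (2 higher, 3 lower of 19) and the interferon response (0 higher, 3 lower of 26).

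With cycloheximide 2852 genes passed for E2, 1406 higher and 1446 lower, of which 118 were at least 2-fold higher and 13 at least 2-fold lower. The share of higher calls was 49.3%. It was 39.1% of 1507 calls after control centring and 59.2% of 2701 after array median centring, so the balance depended on the scaling.

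The difference between the E2 effects with and without cycloheximide, tested as an interaction, was largest for KRT13 (3.62, SE 0.17), which went from 6.33 ± 0.21 to 6.70 ± 0.12 with E2 alone, and for LINC01588 (3.29, SE 0.17). Among genes above the median level ERN1, an endoplasmic reticulum stress sensor, followed with 2.10, then the acyltransferase gene MBOAT1 with 2.02 and the transglutaminase gene TGM2 with 1.96. In the other direction the E2 increase of the centromere protein gene CENPI, from 5.78 ± 0.31 to 7.92 ± 0.073, was not seen with cycloheximide, at 5.45 ± 0.086 and 5.46 ± 0.12 (interaction -2.14, SE 0.16). EXO1 (-2.08), LINC00052 (-2.04), TMPRSS3 (-1.89) and DSCC1 (-1.87) came next under that limit. Without the _x_at and _s_at probe sets TMPRSS3 and DSCC1 were at -0.091 and -0.26, with adjusted p = 0.72 and 0.152.

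PGR showed no detectable difference (-0.0043, SE 0.25, adjusted p = 0.994), and CXCL12 (0.14), PDZK1 (0.38), NRIP1 (-0.33), ESR1 (0.17) and ERBB2 (0.29) did not pass either. PDZK1 passed without vehicle replicate 1 (0.56, adjusted p = 0.00137), and NRIP1 with control centring (-0.52, adjusted p = 0.0269). The E2 increase was smaller with cycloheximide for CCNE2 (-1.70), CDC6 (-1.29), CCNB1 (-0.69), GREB1 (-0.55), E2F1 (-0.37) and TFF1 (-0.35). For GREB1 the mean of the probe sets gave -0.21 (adjusted p = 0.167), and for E2F1 the call was lost without any one of 6 arrays, with adjusted p between 0.0526 and 0.059 (vehicle replicate 2, E2 replicate 2, cycloheximide replicates 2 and 4, and cycloheximide with E2 replicates 3 and 4). The smaller increases of GREB1, TFF1 and CCNB1 went with a higher start, not with a lower E2-treated level. GREB1 stood at 9.86 with cycloheximide and 10.96 with both, against 10.11 with E2 alone. These levels were 13.24, 13.46 and 13.27 for TFF1 and 9.74, 9.75 and 9.74 for CCNB1. The E2 change was shifted upward for IGFBP4 (0.85), CA12 (0.78), BMF (0.57), CCND1 (0.51), XBP1 (0.48), MYC (0.45), CCNG2 (0.41) and MYB (0.38). For CA12, XBP1 and MYC this went with a lower start, not with a higher E2-treated level. CA12 stood at 9.15 with vehicle, 8.30 with cycloheximide, 10.15 with E2 and 10.08 with both. These levels were 10.02, 9.13, 11.18 and 10.77 for XBP1 and 10.31, 9.74, 10.48 and 10.36 for MYC. BMF and CCNG2 fell less with cycloheximide, from lower starts (7.38 against 7.86, and 8.86 against 9.92). IGFBP4, CCND1 and MYB stood higher with both than with E2 alone. Control centring ended the calls of BMF, CCND1, XBP1, MYC, CCNG2 and MYB, with adjusted p between 0.0741 and 0.361.

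Of 45 DNA replication genes 44 had a smaller E2 change with cycloheximide, with a median interaction of -0.96, and so had 36 of 39 mitosis genes (-1.15) and 16 of 19 G1/S regulators (-0.64), CCND1 being higher (44, 36 and 17 adjusted over the list alone). Their adjusted p-values with an estimated correlation were 0.0211, 0.0268 and 0.00894. The E2 change of cholesterol synthesis genes was lower with cycloheximide in 10 of 19 cases (12 adjusted over the list alone), EBP most, by -0.98. Camera gave an adjusted p = 0.0268 with an estimated correlation. For E2-repressed genes the E2 change was higher with cycloheximide in 13 of 20 cases (17 adjusted over the list alone). Camera gave an adjusted p = 0.00075 with an estimated correlation. IL1R1 differed most, by 2.49. This gene was at 7.51 with vehicle and 4.76 with E2. It was at 3.79 ± 0.19 with cycloheximide and 3.54 ± 0.22 with both, below the median gene level of 5.77. Cycloheximide alone lowered 12 and raised 5 of the 20, so a lower start was not separated from a changed E2 response. The E2 change of proliferation inhibitors was higher in 10 and lower in 2 of 18 cases. These counts were 12 and 1 of 22 for ATF4 targets, 19 and 2 of 33 for immediate early genes, and 9 and 2 of 24 for p53 targets. Adjusted over the list alone they were 10 and 2, 12 and 2, 22 and 3, and 10 and 3. Camera gave adjusted p of 0.0305, 0.0305, 0.0218 and 0.0218 with an estimated correlation. The p53 median of 0.20 was small beside the scaling. Control centring lowers every interaction by the same amount, and moved the median of all genes from -0.039 to -0.22.

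The remaining 8 calls for the interaction were lost with an estimated correlation: E2-induced genes (18 higher, 7 lower of 38, 20 and 10 adjusted over the list alone; adjusted p = 0.108 with an estimated correlation), interferon response (11 higher of 26, 14 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation), proteasome subunits (6 lower of 27, 7 adjusted over the list alone; adjusted p = 0.411 with an estimated correlation), and 5 that changed sign with control centring. These were luminal identity (0.14 to -0.047), nonsense-mediated decay targets (0.13 to -0.0565), BCL2 family (0.14 to -0.044), histone genes (0.0765 to -0.11) and tRNA synthetases (0.090 to -0.094), with 4 and 0, 7 and 1, 6 and 3, 8 and 4, and 3 and 0 members higher and lower (5 and 1, 7 and 2, 6 and 3, 8 and 5, and 3 and 0 adjusted over the list alone). Their adjusted p with an estimated correlation were 0.0674, 0.14, 0.284, 0.284 and 0.411.

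The interaction passed for 3916 genes, 1986 above and 1930 below 0. The share above 0 fell from 50.7% to 14.2% with control centring, which shifted the median of all genes from -0.039 to -0.22, and rose to 59.1% with array median centring. Of the 273 genes at least 2-fold higher with E2 alone, 130 also rose with cycloheximide, and for 246 the interaction was called against the increase. For the 88 genes at least 2-fold lower these counts were 49 and 83. These genes were chosen by a contrast that the interaction contains, which favours differences of this sign. Both E2 effects shared 575 higher and 582 lower genes, against 166.6 and 189.6 for independent lists of these sizes. In opposite directions 294 genes were called, against 355.7. The expected counts were taken over all genes, dim ones included, and lie too low if dim genes are seldom called in either contrast. With control centring 315 higher and 272 lower genes were shared, and without _x_at and _s_at probe sets 371 and 382. Across all genes, which are not independent replicates, the changes had a Pearson r of 0.356 and a Spearman rho of 0.1496. A further 653 genes were called higher and 748 lower with E2 only in the presence of cycloheximide, and for 412 and 374 of them the interaction itself was called in that direction.

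**Figure D2:**
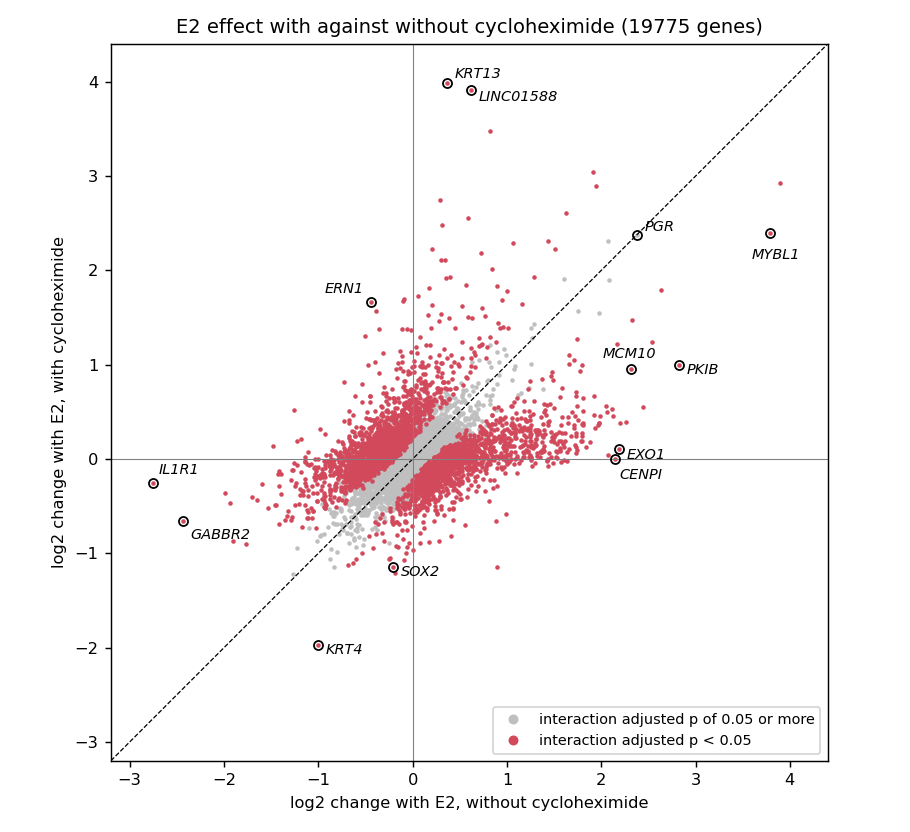
Log2 change with E2 in cells given cycloheximide (y axis) against that in cells not given it (x axis), with 1 point per gene; red points had an interaction adjusted p under 0.05, and the dashed line marks equal changes. PGR lies on the line, KRT13 and LINC01588 far above it, and CENPI and EXO1 near 0 on the y axis.

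**Figure D3:**
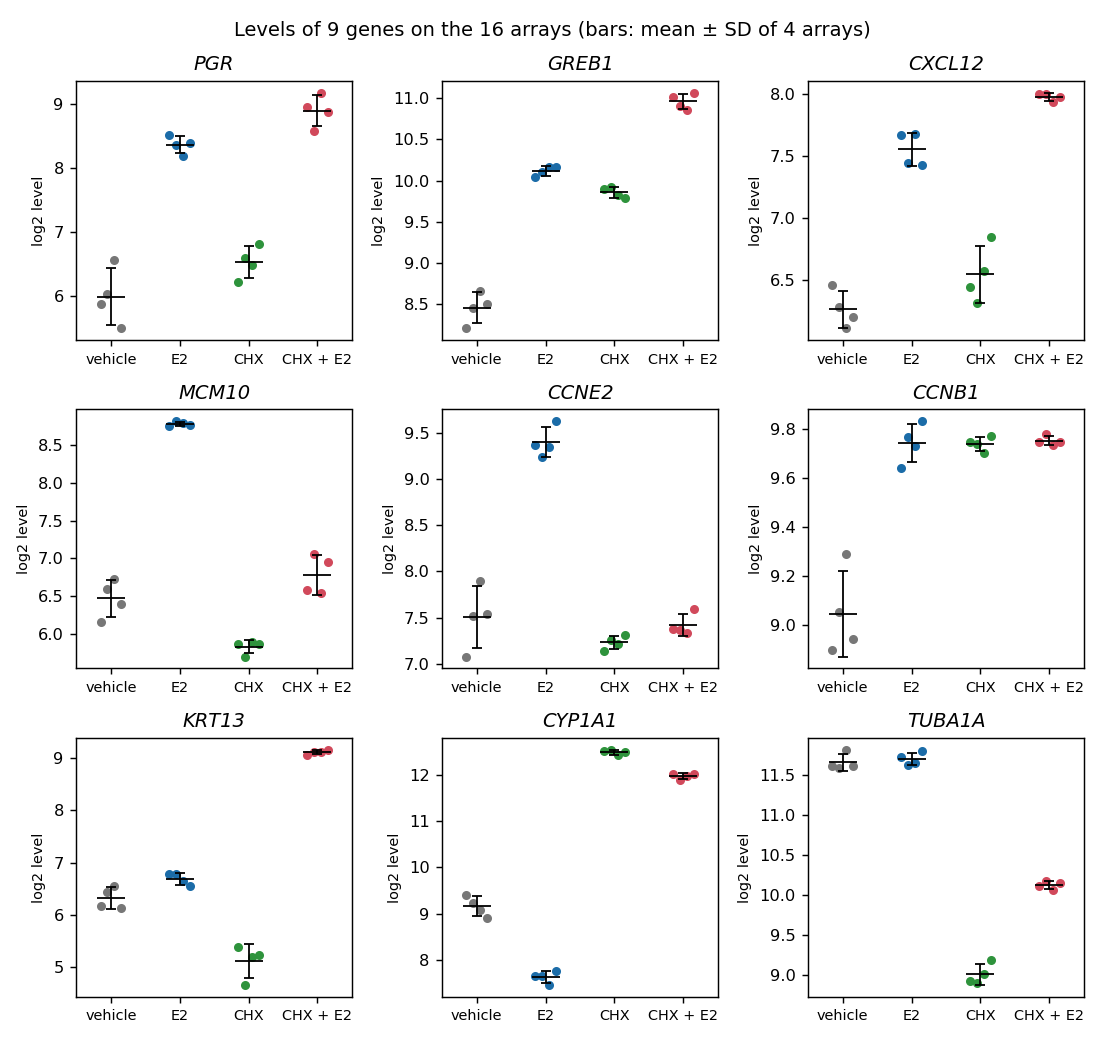
Log2 levels (y axis) of 9 genes on the 16 arrays by group (x axis), with 1 point per array and bars for the mean ± SD of 4 arrays. CCNB1 stood at 9.05 with vehicle and between 9.74 and 9.75 in the other 3 groups, whereas MCM10 was highest with E2 alone at 8.78.

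Cycloheximide alone changed more genes than E2. RGCC, a regulator of cell cycle and complement response, rose from 5.32 ± 0.25 to 10.27 ± 0.047 (log2 change 4.95, SE 0.098). The change was 0.047 (adjusted p = 0.793) without _x_at and _s_at probe sets, where a dimmer probe set is read. KRT4 rose 14.2-fold, from 5.84 ± 0.25 to 9.67 ± 0.08, and the laminin chain LAMB1 from 4.44 ± 0.32 to 7.91 ± 0.081. The calcium-binding protein gene S100A8 rose by 3.44 and PKIB, also raised by E2, by 3.39. DDIT4, an inhibitor of mTOR signalling, fell by 3.18, from 10.17 ± 0.15 to 6.99 ± 0.14, and the alpha tubulin gene TUBA1A fell 6.33-fold, from 11.66 ± 0.11 to 9.002 ± 0.13.

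The other large increases were those of COXFA4L3 (3.90), TMPRSS3 (3.80), C11orf96 (3.53), HS6ST2 (3.46) and SYTL4 (3.34). Without _x_at and _s_at probe sets TMPRSS3 (0.074), C11orf96 (0.23) and SYTL4 (0.29) did not pass. The other large decreases were those of PABIR2 (-3.14), STC1 (-2.95), AKR1C3 (-2.83), DPYSL2 (-2.78), MATN2 (-2.71), ST8SIA4 (-2.69), RFX5 (-2.53) and the stearoyl-CoA desaturase gene SCD (-2.48). MATN2 was at 0.067 (adjusted p = 0.446) without those probe sets. Several E2 targets moved with cycloheximide alone: GREB1 rose 2.63-fold, NRIP1 2.30-fold, MYB 1.93-fold, CCNB1 1.62-fold and TFF1 1.46-fold, and IGFBP4 by 0.84 on the log2 scale. CCNG2 (-1.06), ERBB2 (-1.004), XBP1 (-0.89), CA12 (-0.85), ESR1 (-0.83), MYC (-0.57) and BMF (-0.48) fell. CDC6 (-0.41) and CCND1 (-0.26) fell too, with adjusted p = 0.193 and 0.675 after control centring. PGR (0.54, adjusted p = 0.0169) lost its call with only the groups of the contrast in the fit (adjusted p = 0.052), without cycloheximide replicate 4 (0.44, adjusted p = 0.0656) or vehicle replicate 4 (0.37, adjusted p = 0.0751), and CXCL12 (0.28, adjusted p = 0.0262) without replicate 3 or 4 of either group, with adjusted p between 0.0569 and 0.117. CCNE2 (-0.28, adjusted p = 0.0789), PDZK1 (-0.27, adjusted p = 0.104) and E2F1 (-0.19, adjusted p = 0.0593) did not pass. The mean of the E2F1 probe sets did (-0.21, adjusted p = 0.00722), and without vehicle replicate 1 CCNE2 was at -0.42 (adjusted p = 0.00141) and PDZK1 at -0.44 (adjusted p = 0.000168).

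With cycloheximide alone 18 of 19 cholesterol synthesis genes fell and SC5D rose (the same adjusted over the list alone), with a median of -0.90 and an adjusted p = 0.0118 with an estimated correlation. The sterol-regulated INSIG1 fell by 2.01. Of 21 histone genes 18 rose (18 adjusted over the list alone; adjusted p = 0.0138 with an estimated correlation), H4C8 and H2BC4 most, by 2.81 and 2.76. Of 23 NF-kB targets 17 rose and NFKBIZ fell (19 and 1 adjusted over the list alone; adjusted p = 0.0118 with an estimated correlation), with TNFAIP3 and IL6 higher by 2.30 and 2.28. Mitosis genes rose in 36 of 39 cases and MAD2L1 fell (the same adjusted over the list alone), with a median of 0.75, while DNA replication genes fell in 38 of 45 cases (40 adjusted over the list alone), with a median of -0.64. GINS2 of the second list fell by 2.10, but was at 0.071 (adjusted p = 0.425) without _x_at and _s_at probe sets. Camera gave 5.95e-10 and 5.43e-14 for these 2 lists, and an adjusted p = 0.269 and 0.168 with an estimated correlation.

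Immediate early genes rose in 21 and fell in 7 of 33 cases (23 and 7 adjusted over the list alone; adjusted p = 0.0915 with an estimated correlation), with CCN2 highest at 2.45. The p53 targets rose in 14 and fell in 3 of 24 (15 and 4 adjusted over the list alone; adjusted p = 0.0915 with an estimated correlation), with DDB2 highest at 1.97. ER chaperones fell in 12 and rose in 5 of 19 cases (12 and 5 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation), PDIA4 most, by -1.21. The tRNA synthetases fell in 10 and rose in 2 of 15 (10 and 2 adjusted over the list alone; adjusted p = 0.269 with an estimated correlation). E2-induced genes rose in 22 and fell in 11 of 38 cases and E2-repressed genes fell in 12 and rose in 5 of 20 (22 and 11, and 13 and 5 adjusted over the list alone; adjusted p = 0.396 and 0.181 with an estimated correlation). TXNIP and BCL6 of the second list rose by 2.23 and 2.12. Ribosomal protein genes fell in 20 and rose in 3 of 53 cases (20 and 3 adjusted over the list alone; adjusted p = 0.403 with an estimated correlation), with a median of -0.078 that became 0.13 with control centring. The other 12 lists had no call, among them ribosome biogenesis (18 higher, 9 lower of 36), G1/S regulators (3 higher, 8 lower of 19), ATF4 targets (5 higher, 12 lower of 22), basal and myoepithelial markers (2 and 2 of 10) and fibroblast and immune markers (1 higher, 2 lower of 15). With control centring the medians of the G1/S and ATF4 lists went from -0.19 and -0.1985 to 0.0215 and 0.012.

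Cycloheximide alone changed 9022 genes, 4766 higher and 4256 lower, of which 740 were at least 2-fold higher and 588 at least 2-fold lower. The hybridisation controls were lower with cycloheximide than with vehicle by -0.21 (exact permutation test, two-sided, 4 against 4 arrays, p = 0.0286, the smallest this test can give; adjusted p = 0.114 over 20 tests of array measures), and centring on them moved the median of all genes from 0.019 to 0.23 and the share of higher calls from 52.8% to 79.8%; array median centring gave 56.4%.

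In E2-treated cells cycloheximide raised RGCC, from 4.19 ± 0.15 to 9.64 ± 0.062, with a change of -0.14 (adjusted p = 0.344) without _x_at and _s_at probe sets, CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, 20.5-fold (from 7.63 ± 0.13 to 11.98 ± 0.06), and the transcription factor SOX9 18.4-fold (from 6.11 ± 0.07 to 10.32 ± 0.11). COXFA4L3 and the histone gene H2BC4 rose from levels below the array medians, 4.34 ± 0.12 and 3.96 ± 0.13, to 8.41 ± 0.08 and 7.94 ± 0.11. DPYSL2 fell 11.8-fold, PABIR2 9.92-fold, the replication gene GINS2 8.66-fold, and the DNA repair and checkpoint genes FANCI and TRIP13 fell 8.17-fold and 8.03-fold. Among the genes always reported IGFBP4 rose 3.21-fold, MYB 2.51-fold, NRIP1 1.83-fold, GREB1 1.79-fold and CXCL12 1.34-fold. CCNE2 (-1.98), CDC6 (-1.70), ERBB2 (-0.71), ESR1 (-0.66), CCNG2 (-0.65), E2F1 (-0.56) and XBP1 (-0.41) fell. PGR was higher by 0.53, with an adjusted p = 0.0632 without cycloheximide with E2 replicate 3 and 0.0529 without E2 replicate 3. CCND1 was higher by 0.25, which did not pass with the mean of its probe sets (adjusted p = 0.13), and TFF1 by 0.19, which did not pass with control centring (adjusted p = 0.0996). MYC, CA12, BMF, PDZK1 and CCNB1 did not pass, with changes between -0.12 and 0.12. CCNB1 was higher by 0.67 (adjusted p = 2.52e-06) without _x_at and _s_at probe sets and by 0.34 (adjusted p = 0.00068) with the mean of its probe sets.

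DNA replication genes fell in 44 of 45 cases in E2-treated cells (44 adjusted over the list alone), with a median of -1.68 and an adjusted p = 0.0301 with an estimated correlation, and G1/S regulators fell in 15 and rose in 2 of 19 (16 and 2 adjusted over the list alone; adjusted p = 0.0285 with an estimated correlation), SKP2 most, by -3.63. Mitosis genes fell in 24 and rose in 6 of 39 cases (the same adjusted over the list alone; adjusted p = 0.628 with an estimated correlation). Cholesterol synthesis genes fell in 18 of 19 cases, histone genes rose in 13 and fell in 3 of 21, NF-kB targets rose in 16 and fell in 1 of 23, immediate early genes rose in 26 and fell in 3 of 33, and p53 targets rose in 20 and fell in 2 of 24 (18, 13 and 3, 16 and 1, 26 and 4, and 20 and 2 adjusted over the list alone), with adjusted p of 0.00638, 0.0285, 0.00991, 0.00991 and 0.00638 with an estimated correlation. Calls for E2-induced genes (24 higher, 8 lower of 38), interferon response (16 higher, 2 lower of 26), nonsense-mediated decay targets (10 higher, 3 lower of 19) and ER chaperones (4 higher, 13 lower of 19) were lost, with an adjusted p = 0.0954, 0.419, 0.185 and 0.118 with an estimated correlation (24 and 9, 17 and 2, 10 and 3, and 4 and 14 adjusted over the list alone).

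In E2-treated cells 9727 genes passed, 4610 higher and 5117 lower, of which 964 were at least 2-fold higher and 672 at least 2-fold lower. The share of higher calls, 47.4%, became 54.6% with control centring (4096 and 3409) and 55.7% with array median centring (5155 and 4092), so its side of an even split depended on the scaling. Both cycloheximide effects, which share no array, had 3577 higher and 3278 lower genes in common, and 317 in opposite directions. Independent lists over all genes, dim ones included, would share 1111 and 1101, counts that may lie too low for the same reason. The Pearson r across genes was 0.8445.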

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

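Tests of RNA degradation and compression on vehicle replicate 1, of the mitosis and replication pattern, and of scaling and starting level for the larger E2 increases were chosen after the results were seen. The counts over other splits, the admixture test and the cross-hybridisation test were not.

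For each of the 5 contrasts the real grouping called more genes than any other grouping tried. The other splits mix treated and untreated arrays, so the treatment effect enters their spread and makes low counts likely in advance. For the interaction the permuted residuals likewise still hold the interaction. The counts below therefore rank the real grouping first, but do not measure how many calls chance alone would give. With E2 alone 4936 genes passed, against at most 302 under the other splits of the 8 arrays (35 in all). With limma the highest other count was 0 for E2 with cycloheximide (2852 real, 5277 at an unadjusted p under 0.05), for cycloheximide without E2 (9022 real, 9933 unadjusted) and with E2 (9727 real, 10629 unadjusted), each over 35 splits. It was also 0 for the interaction (3916 real, 6238 unadjusted), over 100 groupings that count the real one beside permutations of the residuals of an additive model. In each case 1 grouping, the real one, gave as many. For the calls shared by both E2 effects (1157 real) the highest other count was 0 over 100 groupings, the real one included. The other splits of the arrays with cycloheximide gave 0 calls to share (limma), so this does not address whether the overlap exceeds chance.

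Vehicle replicate 1 stood apart from the other vehicle arrays. For degraded RNA, 0 of 2 control genes, GAPDH and ACTB, had a 3' minus 5' gap above that of each other array. The other arrays include treated ones with higher GAPDH gaps (up to 0.34), so this does not decide the question. Among the vehicle arrays its GAPDH gap was the highest (0.2095, next 0.2072), and its ACTB gap (0.51) lay within their range. Admixture of E2-treated cells or RNA was argued against by the genes that E2 raised. Over 243 genes at least 2-fold higher with E2 in a fit without vehicle replicate 1, its median deviation was -0.22, whereas admixture needs a value above 0. Over 100 E2-lowered genes, however, it was -0.14, the direction that admixture predicts. Compression at high levels left by the normalisation may have contributed, since deviation and level had a Spearman rho of -0.337, against at most 0.256 in size on the other 15 arrays. No biological explanation was tested.

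Mitosis genes rose and DNA replication genes fell with cycloheximide alone, although both lists rose with E2 alone; camera gave an adjusted p = 0.269 and 0.168 with an estimated correlation, so as lists these calls hold only at the preset one. The mean level of the mitosis list was 7.31 ± 0.23 with vehicle, 8.52 ± 0.055 with E2, 8.05 ± 0.042 with cycloheximide and 8.17 ± 0.0073 with both, and that of the replication list 7.53 ± 0.11, 8.88 ± 0.0079, 6.83 ± 0.020 and 7.20 ± 0.11. An array-wide shift cannot move the gap between both lists, yet the lowest cycloheximide array exceeded the highest vehicle array by 1.22, and with control centring the medians were 0.96 and -0.43. Vehicle replicate 1 alone was excluded, since without it the mitosis median was 0.64, with 36 genes higher and 1 lower, and that of replication -0.74; one multiplicative rise whatever the E2 state was excluded because 36 of 39 mitosis genes had an interaction below 0. A candidate explanation that stays open, untested here, is an effect of cycloheximide on the share of cells in each cycle phase or on the decay of these transcripts.

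KRT13, LINC01588 and 88 other genes at least 2-fold higher with E2 in the presence of cycloheximide had an interaction above 0, with a median of 1.05; for 16 of them the E2 change was below 0 without cycloheximide, 5 of these (ERN1, TGM2, SOX9, MAML3 and BBOF1) with a call, so that for these 5 the direction turned. Cross-hybridisation of a single probe set was argued against, since another probe set was called in the same direction for 69.6% (32 of the 46 genes with another probe set above the median level) and in the opposite direction for 1; the other 44 were not tested, among them KRT13, whose single probe set has an _s_at suffix. A lower start with an equal E2-treated level does not account for the 67 of 90 genes called higher in E2-treated cells with cycloheximide than without. The 90 were chosen by contrasts that hold the arrays with cycloheximide and E2, which favours high levels there. For genes without that call a lower start was not excluded. CA12, for example, started at 8.30 against 9.15 with vehicle, and stood at 10.08 and 10.15 with E2. In total 41 started lower, and the median change was -0.17 at the start and 0.92 with E2. For array scaling, control centring moved the median interaction of all genes from -0.039 to -0.22. It left that of the 90 at 0.86, with 90 of 90 above 0 and 70 still called. Centring shifts every gene by the same amount, and the 90 were chosen for an interaction above 0 (lowest 0.30). This outcome was therefore largely set by the choice of genes. It shows only that the shift given by these controls was smaller than each of the 90 interactions. For the 20 whose call ended, with a median of 0.48 (median SE 0.11) before and 0.29 (0.16) after as the value fell and its SE grew, scaling cannot be told apart, and an effect of cycloheximide on transcript stability or on repressors may act as well but was not tested.

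Single arrays far from the other 3 of their group were found in 50 of 851 groups of values, where the gap to the nearest array, divided by the range, was above the 95% critical value of Dixon's test; chance gives about 1 in 20. Vehicle replicate 1 held 3 of these, SYTL4, FOS and ERN1. SYTL4 (replicate 1, 0.926), FOS (replicate 1, 0.8293), TNFAIP3 (replicate 3, 0.859), ERN1 (replicate 1, 0.831) and BAK1 (replicate 2, 0.922) stood low among the vehicle arrays. EXO1 (replicate 3, 0.924), GDF15 (replicate 2, 0.885), MX1 (replicate 4, 0.837), STC1 (replicate 3, 0.861), TUBA1A (replicate 3, 0.885) and IFI6 (replicate 4, 0.933) stood high among the vehicle arrays. AHRR (replicate 1, 0.837), BMF (replicate 4, 0.901), EPB41L4A-AS1 (replicate 4, 0.865), EGFR (replicate 4, 0.860), PABIR2 (replicate 3, 0.834), SKP2 (replicate 2, 0.876) and ADM (replicate 2, 0.915) stood low among the E2 arrays. RPL37A (replicate 3, 0.894), GDF15 (replicate 3, 0.853) and KRT15 (replicate 2, 0.892) stood high among the E2 arrays. CDC6 (replicate 3, 0.860), MCM10 (replicate 2, 0.887), STC2 (replicate 4, 0.852), H1-2 (replicate 2, 0.964), MBOAT1 (replicate 4, 0.909), NDC80 (replicate 1, 0.880), H2BC21 (replicate 4, 0.848) and BCL6 (replicate 4, 0.904) stood low among the cycloheximide arrays. ATF4 (replicate 2, 0.849) and PSMC6 (replicate 3, 0.894) stood low among the cycloheximide arrays. RBL1 (replicate 4, 0.841), PSMD1 (replicate 3, 0.941) and C11orf96 (replicate 1, 0.838) stood high among the cycloheximide arrays. CYP26B1 (replicate 2, 0.963), MYC (replicate 1, 0.863), TOB1 (replicate 2, 0.975), RPL34 (replicate 4, 0.916), SC5D (replicate 2, 0.840), BAD (replicate 4, 0.854) and DPYSL2 (replicate 3, 0.834) stood low among the arrays with cycloheximide and E2. CCNE2 (replicate 4, 0.839), DHCR7 (replicate 2, 0.859), CD79A (replicate 1, 0.903), P4HA2 (replicate 2, 0.838), ALDOC (replicate 2, 0.907), EBP (replicate 2, 0.841), H1-10 (replicate 1, 0.851) and SOX9 (replicate 4, 0.838) stood high among the arrays with cycloheximide and E2. The GAPDH 3' minus 5' gap was highest on replicate 1 with cycloheximide and E2, at 0.34 against a mean of 0.20 on the other 3 arrays (0.865).

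Differences between the E2 effects with and without cycloheximide passed the interaction test for 138 of 184 genes looked at. Named genes were picked partly for large interactions or E2 changes, so this share was raised by the choice. Over all genes 3916 of 19775 (19.8%) passed. With camera at the preset correlation 17 of 24 lists passed, of which 9 kept their call with an estimated one. Control centring ended the calls of BAK1, BMF, CARS1, CCND1, CCNG2, CD14, CDKN1A, EGFR, FOXO1, GADD45B, HSPA5, MYB, MYC, NFKBIA, RRP12, SARS1, TNFAIP3, UTP20 and XBP1, with adjusted p between 0.0513 and 0.556. Without _x_at and _s_at probe sets DSCC1, EGFR, HRK, LTB, NFKBIA and TMPRSS3 lost theirs, and RRP12 (-0.22), GADD45B (-0.038), NCL (0.071) and CDKN2D (0.049) were at values of the opposite sign without a call. With the mean of the probe sets BAD, CDKN2D, COL1A1, EGFR, FOXO1, GREB1, NCL, NFKBIA, TRA2B and XBP1 lost theirs and RRP12 was at -0.0048. CENPI (-2.14), EXO1 (-2.08), LINC00052 (-2.04), TMPRSS3 (-1.89), DSCC1 (-1.87), PKIB (-1.83), TK1 (-1.72), CCNE2 (-1.70) and NDC80 (-1.67) had lower E2 changes with cycloheximide. ANLN (-1.65), E2F7 (-1.60), NUF2 (-1.45), MYBL1 (-1.39), MCM10 (-1.36), SYTL4 (-1.30), CDC6 (-1.29), MAD2L1 (-1.27) and PDK1 (-1.26) differed in the same direction. LDHA (-1.10), CDCA8 (-0.99), EBP (-0.98), KRT4 (-0.96), SOX2 (-0.94), TFF3 (-0.90), PCP4 (-0.85), BNIP3 (-0.85) and FOS (-0.84) were also lower. UGT2B15 (-0.84), DDB2 (-0.84), ADAMTS19 (-0.81), H2AX (-0.80), ACAT2 (-0.79), H1-10 (-0.73), CCNB1 (-0.69), MCM5 (-0.64) and GREB1 (-0.55) had lower E2 changes with cycloheximide. H2AZ1 (-0.54), PSMC3 (-0.52), SDF2L1 (-0.51), BAD (-0.51), SGK1 (-0.50), CDKN2D (-0.47), CAB39L (-0.47), IDH1 (-0.46) and GRB14 (-0.46) differed in the same direction. CRELD2 (-0.45), PGM5 (-0.44), FBL (-0.42), LTB (-0.39), TRA2B (-0.37), CD3E (-0.37), E2F1 (-0.37), PSMB3 (-0.37) and TFF1 (-0.35) were also lower. SHMT2 (-0.33), NCL (-0.33), PSMD14 (-0.33), CDKN1B (-0.30), SC5D (-0.29), TRIAP1 (-0.28) and HK2 (-0.27) had lower E2 changes with cycloheximide. KRT13 (3.62), LINC01588 (3.29), IL1R1 (2.49), ERN1 (2.10), MBOAT1 (2.02), TGM2 (1.96), GABBR2 (1.79), AHRR (1.64) and SNAI2 (1.62) had higher E2 changes with cycloheximide. UPK1A (1.47), KRT15 (1.38), SALL4 (1.33), TNS3 (1.30), SLC26A2 (1.22), PSCA (1.22), H2BC4 (1.22), EGR1 (1.20) and CCN2 (1.16) differed upward too. H2BC21 (1.16), LINC01016 (1.13), PFKFB3 (1.09), GRHL3 (1.04), CYP1A1 (1.02), VXN (0.99), HSPB8 (0.98), TP53INP1 (0.97) and CYP26B1 (0.95) were also higher. IFIT3 (0.95), P4HA2 (0.94), STC2 (0.91), OAS2 (0.88), ELF3 (0.88), RBM24 (0.87), DDIT4 (0.87), STON1 (0.87) and IGFBP4 (0.85) had higher E2 changes with cycloheximide. TP53I3 (0.84), SLC7A11 (0.79), CA12 (0.78), MX1 (0.78), COL1A1 (0.77), GDF15 (0.75), BAK1 (0.67), HRK (0.67) and EPB41L4A-AS1 (0.64) differed upward too. EGFR (0.62), ALDOC (0.59), BMF (0.57), BIK (0.57), JUNB (0.56), GADD45B (0.54), CDKN1A (0.53), FOXO1 (0.51) and CCND1 (0.51) were also higher. FHL2 (0.50), PMAIP1 (0.50), XBP1 (0.48), KLF4 (0.46), CDKN2B (0.45), MYC (0.45), UTP20 (0.43), TOB1 (0.42) and GADD45A (0.42) had higher E2 changes with cycloheximide. CCNG2 (0.41), CARS1 (0.40), H2AC8 (0.39), MYB (0.38), SARS1 (0.38), CD14 (0.37), RRP12 (0.35), TNFAIP3 (0.32) and WARS1 (0.31) differed upward too. HSPA5 (0.31), NOB1 (0.30), NFKBIA (0.30), SLC7A5 (0.30) and DDX10 (0.29) were also higher. RBL1, CD14, CD3E, SLC7A11 and the genes LINC01588, SKP2, TMPRSS3, IL1R1, H2BC4, CCN2 and VXN named in the report had mean levels below the medians of their arrays in at least 1 group, where signal above background is not shown. Lists with a median interaction below 0 were Mitosis (-1.15), DNA replication (-0.96), G1/S regulators (-0.64), Cholesterol synthesis (-0.28) and Proteasome subunits (-0.11). Those above 0 were Histone genes (0.076), tRNA synthetases (0.090), Nonsense-mediated decay targets (0.13), Luminal identity (0.14), BCL2 family (0.14), p53 targets (0.20), E2-induced genes (0.27), Immediate early genes (0.31), ATF4 targets (0.31), Proliferation inhibitors (0.36), Interferon response (0.40) and E2-repressed genes (0.49). Of these 17 lists, E2-induced genes, interferon response, proteasome subunits, luminal identity, nonsense-mediated decay targets, BCL2 family, histone genes and tRNA synthetases lost the call with an estimated correlation (adjusted p between 0.0674 and 0.411), and the last 5 changed sign with control centring.

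Probe sets without a gene symbol, 11721 in number, belong to no gene of the report and also carried signal. With limma 1038 of them passed for E2 without cycloheximide, 518 for E2 with it and 2995 for cycloheximide without E2, adjusted over all 54613 probe sets that are not array controls.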

How the results depend on the processing

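Array weights were added after the data were seen; the other alternatives were planned. Of 13022 values for 527 gene results, 12660 kept direction and side of the threshold, 302 lost their call, 31 gained one and 29 reversed. Of 3115 values for 120 list results these counts were 2966, 98, 36 and 15, and 38 of the 98 losses came with the estimated correlation.

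Counts with 1 array left out ran from 4419 to 5299 for E2 without cycloheximide, 2208 to 3371 for E2 with it, 3403 to 4840 for the interaction, 8527 to 9313 for cycloheximide without E2, 9142 to 10267 with E2, and 978 to 1263 for shared calls. Each highest count was reached without vehicle replicate 1. Array weights, which gave that array 0.293, raised the counts to 5416, 3539, 4937, 9491, 10335 and 1331. With the replicate number as a block they were 4995, 2915, 3999, 9110, 9823 and 1168; the numbers do not pair the arrays, with residual correlations of -0.17 to 0.30 and 4 arrays closest to their own number.

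Every probe set tested by itself gave 9053, 4760, 7023, 20448 and 21330 calls in the 5 contrasts, since more units were tested. A 2-fold minimum gave 361, 131, 281, 1328 and 1636, and 31 shared, by its construction. Shared calls were 753 without _x_at and _s_at probe sets, where fewer genes were tested. Control centring gave 1507 calls for E2 with cycloheximide and 587 shared; the cause was not tested. The remaining counts under the other alternatives stayed within 1.5 times those reported. The filter on dim genes gave no value for genes at or below the median level, and a fit of only the groups of the contrast is the same fit for the interaction.

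Reversed values follow, and the cause was not tested. With the mean of the probe sets EGFR was at 0.0185 for E2, RRP12 at -0.0048 for the interaction, RPS15 (-0.0089), RPS29 (-0.27) and SEC61B (-0.061) for cycloheximide, and RPS15 at -0.0083 for cycloheximide with E2.

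Without _x_at and _s_at probe sets, E2 values were UGT2B15 -0.090, CDKN2D -0.046, GDF15 0.013 and EGFR 0.36, and with cycloheximide LTB 0.049 and ITGB4 0.022. Interaction values were CDKN2D 0.049, RRP12 -0.22, NCL 0.071 and GADD45B -0.038. Cycloheximide values without E2 were MATN2 0.067, GINS2 0.071, RPS15 -0.21, RRP12 -0.22, YARS1 -0.51, EGFR 0.018 and COL3A1 0.003, the last at levels below the array medians. With E2 they were RGCC -0.14, RPS15 -0.18, RRP12 -0.44, POLR1B 0.055, YARS1 -0.59 and HERPUD1 -0.19.

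Control centring reversed the medians of ATF4 targets (0.0155) and histone genes (0.11) for E2; of tRNA synthetases (-0.094), nonsense-mediated decay targets (-0.0565), histone genes (-0.11), BCL2 family (-0.044) and luminal identity (-0.047) for the interaction; and of G1/S regulators (0.0215), ribosomal proteins (0.13) and ATF4 targets (0.012) for cycloheximide. The histone list with E2 was also above 0 without E2 replicate 2 (0.031) or 3 (0.004), without vehicle replicate 1 (0.053) or 4 (0.019), and with array weights (0.025), while the lowest value with 1 array left out was -0.062, without E2 replicate 4.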

Other observations

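Genes of this part were chosen after their values were seen, and so was the test of the hypothesis.

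Tubulin transcripts were lower with cycloheximide alone. Of 10 tubulin genes above the median level 8 fell and 0 rose with limma; with control centring 7 fell and TUBB2A rose. TUBA1A (-2.66), TUBB (-2.31), TUBA1B (-1.90), TUBA1C (-1.47), TUBB4B (-1.29) and TUBB3 (-1.24) fell most, all read by _x_at or _s_at probe sets that can share sequence within the family. TUBA4A (-0.58) fell too, and TUBB6 (-0.23) was at -0.018 without a call after control centring. TUBB2A (0.062, adjusted p = 0.488) and TUBA4B (0.044, adjusted p = 0.791) did not pass. TUBB2B rose from 3.03 to 4.37, both below the array medians, where signal above background is not shown.

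Genes known to be induced through the aryl hydrocarbon receptor moved both ways with cycloheximide alone: CYP1A1 (3.34), TIPARP (1.57), CYP1B1 (0.89) and AHRR (0.73) rose, and NQO1 fell by 0.64. The arrestin-like genes ARRDC4 and TXNIP rose by 3.27 and 2.23, the calcium-binding protein genes S100A8 and S100A9 by 3.44 and 2.18, and the retinal reductase gene DHRS3 by 2.17.

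A hypothesis was that the log2 increase with E2 is smaller with cycloheximide only for members of the DNA replication, mitosis and G1/S lists. It was argued against: of 196 genes at least 2-fold higher with E2 and outside these lists, 86.7% (170) had a smaller increase with cycloheximide, as had 76 of 77 genes inside them. Medians went from 1.34 to 0.30 outside and from 1.40 to 0.27 inside, and 97 and 33 genes were still called with cycloheximide. These genes were chosen by a contrast that the interaction contains, which favours smaller increases in both sets. The 196 also hold cell cycle genes that are in no list, such as CENPI (-2.14) and EXO1 (-2.08), so a loss limited to cell cycle genes as a class was not tested. A smaller log2 increase can also come from a higher start with cycloheximide, which these counts do not separate from a lower E2-treated level. PKIB, for example, went from 7.57 to 10.40 with E2 alone and from 10.96 to 11.96 with cycloheximide.

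Measures of the arrays were compared between groups with 20 exact permutation tests of 4 against 4 arrays, whose smallest possible p is 0.0286. That p was reached by the hybridisation controls (-0.21) and the ACTB 3' minus 5' gap (-0.14) for cycloheximide minus vehicle, the GAPDH gap (0.087) and the array median (-0.055) for cycloheximide with E2 minus E2, and the array median (-0.025) for cycloheximide with E2 minus cycloheximide; none passed adjustment (exact test, adjusted p = 0.114 each).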
